A study of Mus musculus with 6 samples.

How the data were processed

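The series holds 6 single-colour Affymetrix arrays of total RNA from E10 cells, an epithelial line from mouse lung that is not transformed. The cells grew in medium with 10% serum in plates of 6 wells and were infected at 80 to 90% confluency, per the labels' protocols. The titles give 3 biological replicates with a lentivirus that over-expresses miR-129 and 3 with a control lentivirus titled Gfp. They do not say whether the replicates came from separate infections or days, so the p-values measure only the spread between these samples.

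The deposited values are linear signal intensities per probe set, made with MAS5 per the submitters' processing notes. The software version and the scanner settings are not given in the sources used here. On every array the mean of the deposited intensities without the lowest and highest 2% was 500.0, so each array had been scaled to that level. MAS5 detection calls were not used here, so a low signal could not be told from background by a call. No other values were used, and 0 columns lacked a sample.

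Probe sets were named from the platform's annotation through gene IDs and the RefSeq gene table of assembly GRCm38.p6. Of 45101 probe sets, 64 control sets were left out of the tests. Of the other 45037, 34945 had exactly 1 gene symbol, 932 had several and 9160 were unnamed here. The gene IDs of 34754 probe sets were in the RefSeq gene table, and 0 symbols had to be updated.

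Signals were transformed as log2(signal + 16), and no further scaling was applied. A fold change on this scale understates the change of genes with low signals. Probe sets were kept when their mean over all 6 arrays was at or above the 40th percentile, which is a log2 value of 5.46 or a signal of 28.2. This left 27022 probe sets. Each gene was represented by its kept probe set with the highest mean, which gave 12287 genes, of which 5851 had several kept probe sets. The groups were compared with limma 3.58.1 (lmFit and eBayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of single genes are from limma and two-sided. The number of arrays limits the precision, and the fit had 4 residual degrees of freedom.

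The gene lists, 24 in number with 534 entries, were written before the data were examined. They cover cyclins and kinases of G1 and S entry, CDK inhibitors and pocket proteins, DNA replication, mitosis, p53 targets, the interferon response, NF-kB and cytokine genes, epithelial, mesenchymal, alveolar type I, alveolar type II and club cell, macrophage and leukocyte, and fibroblast and endothelial markers, the unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia targets, NRF2 targets, microRNA machinery, ERK pathway feedback and immediate early genes, apoptosis regulators, TGF-beta and YAP targets, extracellular matrix and proteases, cytosolic ribosomal proteins, and genes reported as miR-129 targets. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 24 lists. A further 6 lists, written after the largest changes were seen, were adjusted among themselves. The fit without a variance trend was also used without one in camera; the robust fit has no counterpart there. Members with no kept probe set of exactly 1 symbol were not analysed here.

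The genes named are those of a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, without clone-like names, then Cdk6, and up to 4 members of each list with the smallest p-values past the threshold. A gene among the largest falls is not reported here. Genes named outside this rule, where a count was small or probe sets disagreed, were chosen after their values were seen.

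Array quality was described with the 3′ over 5′ signal ratios of the control probe sets for Gapdh, Actb and the spiked-in bacterial transcripts dap, lys and phe. These ratios rise when labelled RNA is shortened at its 5′ side. They were compared with an exact two-sided permutation test, for which 3 arrays against 3 cannot give a p below 0.1.

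The steps were tested on simulated data before use. In 12287 simulated genes with 200 changed ones, the fit of miR-129 against control lentivirus recovered 44% of changes of 0.5, 58% of 0.75, 66% of 1 and 90% of 1.5 on the log2 scale, and 1.5% of its calls were false. The simulated genes were independent, and far fewer changed than the 5170 called in the data. These rates therefore check the steps and do not describe the real fit. Alternatives covered quantile normalization, median-centring, the pseudocount, the minimum, the variance model, the replicate number as a block, the mean of a gene's probe sets, other thresholds and each array left out. After the data were seen, 2 alternatives were added: the log2 Gapdh ratio as a covariate, and the arrays with the highest and the lowest ratio (miR-129 replicate 1 and control replicate 3) left out together. A planned test of miR-129 seed matches in 3′ untranslated regions was not run, because such sequences were not used here. Tables were prepared with pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9, in Python 3.11.15.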

Results

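Messenger RNA levels were measured in E10 mouse lung epithelial cells infected with a lentivirus expressing miR-129 or with a control lentivirus, with 3 arrays in each group. The mean median signal per array was 51.0 ± 4.40 with miR-129 and 56.0 ± 0.321 with control (SD, n = 3 each). Over the kept probe sets, Pearson's r across probe sets, which are not independent replicates, was 0.979 to 0.986 within groups and 0.955 to 0.971 between groups. The first principal component held 54.7% of the variance and placed the groups on opposite sides. The Gapdh 3′ over 5′ signal ratio, which shifts with RNA quality and with labelling, was 5.78, 2.93 and 2.84 on the miR-129 arrays and 1.60, 2.51 and 1.05 on the control arrays. Its mean was 3.85 ± 1.67 against 1.72 ± 0.737 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give, and 0.35 after adjustment over 7 quality measures). The ratio of the spiked-in lys transcript, which does not come from the cells, was 4.60 ± 1.77 against 2.56 ± 0.290 (exact two-sided permutation p = 0.1). The level of miR-129 itself was not analysed here.

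The comparison of miR-129 with control lentivirus asks which transcripts differ when the microRNA is over-expressed. Genes of mitosis and DNA replication fell, and targets of the tumour suppressor p53 rose. All 37 measured mitosis genes and 34 of 41 replication genes fell, while 14 of 21 p53 targets rose (mitosis and p53 lists: adjusted p = 0.178 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases and a p53 target, rose 4.78-fold, from 1992 ± 48.7 to 9642 ± 1271 (SD, n = 3 each; limma adjusted p = 2.53e-08). Cdk6, the kinase proposed as a direct target of miR-129, did not pass the test at the mRNA level.

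Of 12287 genes, 5170 (42.1%) changed, of which 2911 rose and 2259 fell. The share that rose was 56.3%, against 48.1% with the mean of each gene's probe sets, where more fell than rose, and 65.4% after median-centring. A change of at least 2-fold was seen in 284 of the genes that rose and 287 of those that fell. The median log2 fold change of all genes was 0.01. The 3 arrays of each group did not overlap for 6246 genes (50.8%), where chance gives 10%. Among the 27022 probe sets, 4026 rose and 4149 fell, and 744 of the 4389 tested probe sets without a single symbol changed. With the Gapdh ratio as a covariate, 2927 genes changed. Of the 5170 genes called without it, 2766 were still called in the same direction and 0 in the opposite one.

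Cdk6 encodes a kinase that acts with D-type cyclins in G1, and the study is known to propose it as a direct target of miR-129. Its brightest probe set had signals of 7172 ± 378 with miR-129 and 6727 ± 256 with control (SD, n = 3 each). This is a ratio of 1.07 with a 95% confidence interval of 0.959 to 1.18 (limma adjusted p = 0.355). A dimmer probe set had 3106 ± 138 and 3299 ± 138, a ratio of 0.942 with an interval of 0.843 to 1.05 (limma adjusted p = 0.413). A further Cdk6 probe set lay below the minimum, with mean signals of 22.9 and 24.7. In this fit, which is without the Gapdh ratio, the 95% intervals of the kept probe sets reached no lower than 0.843 of control. The arrays say nothing of Cdk6 protein.

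The largest rises included genes with high and with very low control signals. Saa3, an acute phase protein, rose from 393 ± 37.4 to 1851 ± 251 (limma adjusted p = 1.51e-07), and Hoatz, a gene of motile cilia, from 104 ± 5.10 to 732 ± 128 (limma adjusted p = 1.7e-07). The log2 fold changes of Fcgbp, Cbr2, Col10a1 and Sp110 were 2.35, 2.35, 2.34 and 2.39, from mean control signals of 38.6, 9.77, 9.20 and 43.5. The kept Sp110 probe set had signals of 379, 463 and 141 on the miR-129 arrays. Its other probe sets lay below the minimum, with log2 fold changes of 0.10 and −0.02. Tcstv1, Usp17la and Pramel18, members of multigene families whose near-identical copies the probe sets may not separate, rose by 3.29, 2.46 and 2.34. The mean control signals of Cbr2, Col10a1, Pramel18 and Tcstv1 (17.4) lay below the minimum of 28.2, so the size and rank of their changes depend on the 16 added to each signal. Tcstv1, Usp17la and Pramel18 were lowest among the miR-129 arrays on replicate 3, where Tcstv1 had 101, against 484 and 509 on the others. With the Gapdh ratio as a covariate, Tcstv1 passed (limma adjusted p = 0.0325), while Usp17la (0.246) and Pramel18 (0.0979) did not. All 3 estimates were smaller with the ratio. Tcstv1 had 2.18 ± 0.65 (SE) against 3.29 ± 0.49 without it, Usp17la 1.49 ± 0.86 against 2.46 ± 0.58, and Pramel18 1.93 ± 0.78 against 2.34 ± 0.49. Usp17la also did not pass without the arrays of extreme ratio (0.058) or with a robust variance model (0.0624), and over its alternatives the adjusted p ran from 1.49e-06 to 0.246. Without miR-129 replicate 3 the log2 fold changes of Usp17la and Tcstv1 were 3.42 and 4.01.

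Several genes fell 4-fold or more. Plp2, a membrane protein, fell from 7388 ± 596 to 1453 ± 131 (limma adjusted p = 2.53e-08). Casp6, an effector caspase, had a log2 fold change of −2.33, Zfp91 −2.41, Emp1 −2.06, Rell1 −2.05 and Slc29a1, a nucleoside transporter, −2.04, and Slc43a3 fell from 1099 ± 27.9 to 264 ± 31.5. Other probe sets gave smaller values for Zfp91 (−1.16 and −0.65) and for Emp1 (−0.75, limma adjusted p = 0.092). Ctse, a protease, fell by 2.33 on its brightest probe set, whereas its other probe set had 0.04. Acsl4, which activates arachidonic acid, had −2.08 and −2.63 on 2 probe sets but rose by 1.29 on the third (limma adjusted p = 1.66e-05). Of 5851 genes with several kept probe sets, 177 had probe sets that passed in opposite directions.

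**Figure D1:**
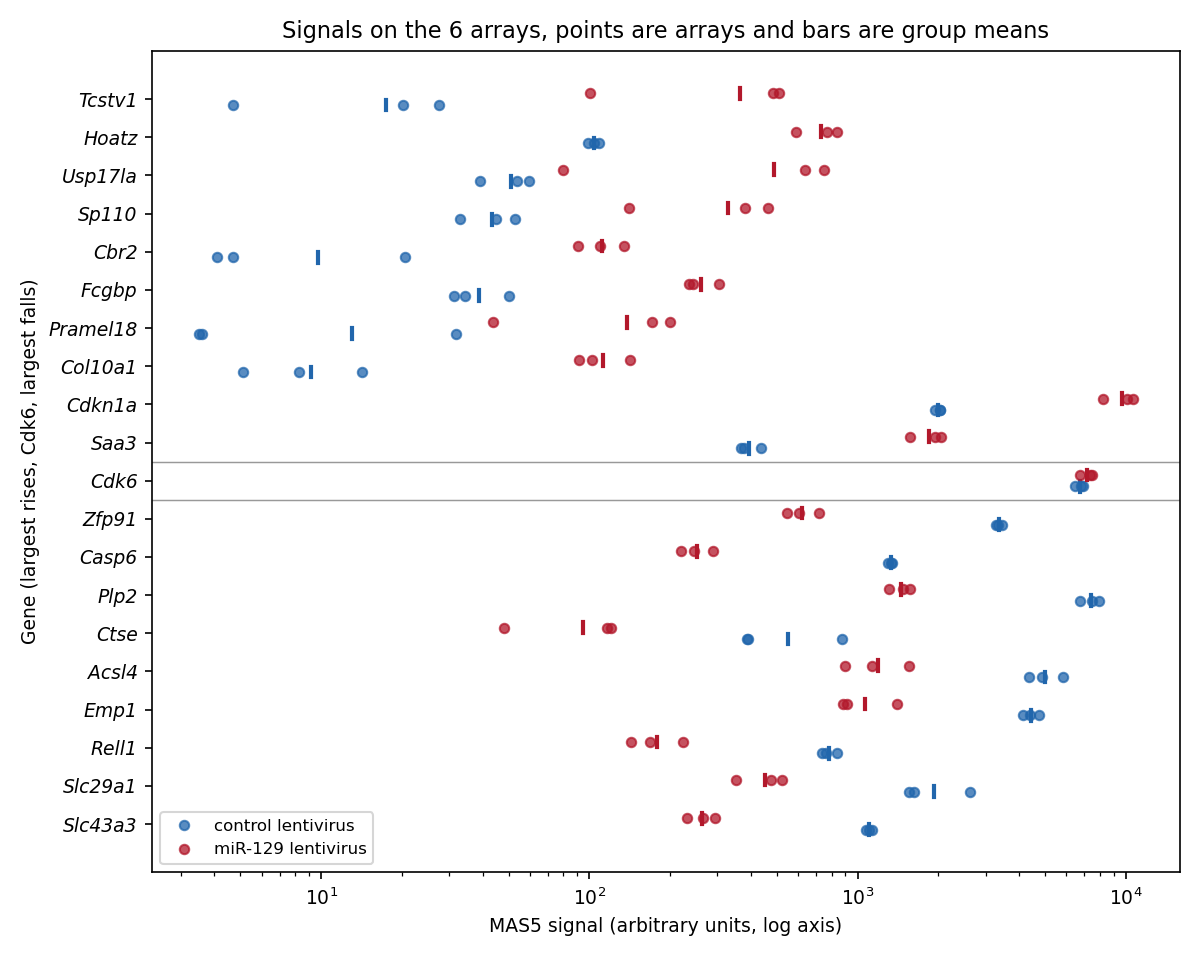
MAS5 signal in arbitrary units (log axis) of the genes with the largest rises, Cdk6 and genes among the largest falls, with a point per array and a bar at each group's mean. Cdkn1a lay between 8207 and 10624 on the miR-129 arrays and between 1936 and 2022 on the control arrays, while the groups overlapped for Cdk6.

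Mitosis genes fell as a set. All 37 measured members fell, also when adjusted over the list alone (37), with a median log2 fold change of −0.75 (camera adjusted p = 7.38e-21; adjusted p = 0.178 with an estimated correlation). Nek2, a kinase of the centrosome, fell from 2058 ± 179 to 708 ± 40.9 (limma adjusted p = 3.26e-07). Cenpf, of the kinetochore, fell by 1.22, Kif11, a motor of the spindle, by 1.29, and Birc5, of the chromosomal passenger complex, by 0.97 on the log2 scale. On the same arrays the Gapdh ratio was higher with miR-129, and with it as a covariate 36 mitosis genes fell.

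DNA replication genes fell as well, with 34 of 41 members lower, Dut higher and 6 not passing. Adjusted over the list alone, 34 fell and 2 rose. The median was −0.58 (camera adjusted p = 6.6e-14), and this was the only list of the 24 past the threshold with an estimated correlation (0.046). Tk1, thymidine kinase, fell from 2918 ± 246 to 742 ± 139 (limma adjusted p = 4.26e-07). Cdc6, which licenses origins, fell by 1.15, Rfc5, of the clamp loader, by 1.10, and Ung, uracil DNA glycosylase, by 1.36 on the log2 scale. In the model with the Gapdh ratio, 30 of these genes fell.

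Among 18 cyclins and kinases of G1 and S entry, 9 fell and 3 rose, the same counts as when adjusted over the list alone. Dbf4, the activator of the Cdc7 kinase, fell from 6353 ± 76.4 to 3402 ± 140, Ccna2 (cyclin A) by 0.93, Cdk4 by 0.76 and Myc by 0.76 on the log2 scale. The 3 that rose were Ccnd2 (0.71), Ccnd1 (0.27) and Cdc25a (0.22); the first 2 encode D-type cyclins. The median was −0.24 (camera adjusted p = 0.049; adjusted p = 0.287 with an estimated correlation), and the call was lost without miR-129 replicate 1 (−0.20, 0.0559) or without miR-129 replicate 2 (−0.20, 0.0547). It was also lost without a variance trend (0.0733), and over its alternatives the adjusted p ran from 0.0183 to 0.103. In the model with the Gapdh ratio, 6 members fell. Of 9 CDK inhibitors and pocket proteins, 2 rose and 4 fell, also when adjusted over the list alone (2 and 4). Cdkn1a and Cdkn2b (0.64) rose, whereas Cdkn2d fell by 1.14 and Cdkn1b by 0.40. Cdkn2b did not pass with the Gapdh ratio as a covariate (limma adjusted p = 0.057), nor Cdkn1b as the mean of its probe sets (0.58). The list's median was −0.31 and its mean 0.01, and the camera test, with the sign of the median, did not pass (adjusted p = 0.618).

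Of 21 p53 targets, 14 rose, 0 fell and 7 did not pass, with 14 also adjusted over the list alone. The median was 0.69 (camera adjusted p = 1.16e-06; adjusted p = 0.178 with an estimated correlation). Besides Cdkn1a, which is also on the list of CDK inhibitors, the death receptor gene Fas rose from 947 ± 65.2 to 2738 ± 292 (limma adjusted p = 4.1e-07). Ccng1, cyclin G, rose 2.04-fold to 23261 ± 1012 on its brightest probe set, and Zmat3 from 1126 ± 82.0 to 2687 ± 96.1. Other kept Ccng1 probe sets rose 4.67-fold and 1.88-fold. Mdm2, the ubiquitin ligase of p53, had a log2 fold change of 0.11 (limma adjusted p = 0.282), and Bbc3, a pro-apoptotic target, −0.14 (limma adjusted p = 0.482). The Gapdh ratio in the model left 14 p53 targets higher. Among 17 apoptosis regulators, 7 rose and 2 fell, also when adjusted over the list alone (7 and 2), with Apaf1 (0.86) and Casp8 (0.51) higher and Bcl2l11 lower (−0.53). As means of their probe sets, Apaf1 did not pass (limma adjusted p = 0.134) and Bcl2l1, 0.39 on its brightest probe set, was −0.35 and did not pass. The list's median was 0.19 (camera adjusted p = 0.245).

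Interferon response genes rose, with 13 of 27 members higher, 1 lower and 13 not passing, and the same counts adjusted over the list alone. The median was 0.53 (camera adjusted p = 0.00168; adjusted p = 0.178 with an estimated correlation). Tap1, the peptide transporter of antigen presentation, rose from 165 ± 3.05 to 544 ± 61.8 (limma adjusted p = 1.42e-06). Ifi35 rose by 1.21, Ddx58, the RNA sensor RIG-I, by 1.09 and Irgm1 by 0.84 on the log2 scale, whereas the chemokine gene Cxcl10 fell by 1.42. In the model with the Gapdh ratio, 9 members rose. Of 20 NF-kB and cytokine genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.00451; adjusted p = 0.178 with an estimated correlation). Besides Saa3, Il6 rose from 381 ± 31.1 to 1110 ± 71.7 (limma adjusted p = 5.32e-07), Ccl2 by 0.76 and Ccl7 by 0.73 on the log2 scale, while Cxcl5 (−0.59) and Csf3 (−0.94) fell. With the covariate, 9 rose.

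Genes reported as miR-129 targets, a list fixed before the values were seen that includes Cdk6, went down more often than up. Of 12 measured members, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of −0.28 (camera adjusted p = 0.0487; adjusted p = 0.288 with an estimated correlation). Ets1, a transcription factor, fell from 3821 ± 231 to 1121 ± 115 on its brightest probe set (limma adjusted p = 1.22e-07), and by 1.17 on the next, while 2 dimmer probe sets had 0.09 and 0.47 and did not pass. Sox4 fell by 0.67 and Ccp110, a centriole protein, by 0.71, and Fndc3b rose by 0.61 on the log2 scale. The list's call was lost without miR-129 replicate 2 (−0.19, 0.0547) and without a variance trend (0.0733; range over its alternatives 0.0206 to 0.103), and with the Gapdh ratio as a covariate 3 members fell. Of 16 genes of the microRNA machinery, 2 rose and 4 fell, as when adjusted over the list alone (2 and 4). Dicer1 (1.99-fold) and Ago2 (0.41 on the log2 scale) rose, and Dcp2 (−1.34) and Xpo5 (−0.57) fell; the median was −0.02 (camera adjusted p = 0.614), and Dcp2 and Xpo5 did not pass as means of their probe sets.

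Extracellular matrix and protease genes rose in 12 of 25 cases and fell in 1, Thbs1, with the same counts adjusted over the list alone. The median was 0.24 (camera adjusted p = 0.0214; adjusted p = 0.203 with an estimated correlation). Col5a1 rose by 0.66, Timp2 by 0.68, Col4a2 by 0.62 and Plat, the tissue plasminogen activator, by 0.75 on the log2 scale. As means of their probe sets, Col5a1 did not pass (0.00), Timp2 was −0.20 and the list was not called (camera adjusted p = 0.122; range over its alternatives 0.00607 to 0.122). With the Gapdh ratio as a covariate, 10 members rose. Of 20 TGF-beta and YAP targets, 6 rose and 5 fell (6 and 6 adjusted over the list alone), among them Tgfb2 (1.20), Tgfbr2 (0.85) and Ccn2 (0.55) higher and Thbs1 lower (−0.66). A dimmer Tgfbr2 probe set rose by 2.31, from a mean control signal of 38.6. The TGF-beta and YAP list had a median of −0.05, a mean of 0.01 and a camera test in the direction of the mean (adjusted p = 0.959).

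Markers of cell types moved in both directions. Of the markers with a probe set, the minimum kept 5 of 13 for alveolar type II and club cells and 6 of 14 for fibroblast and endothelial cells. It kept 7 of 13 macrophage and leukocyte markers and 13 of 22 epithelial ones, against 16 of 17 mesenchymal and 9 of 10 alveolar type I markers. Of 16 mesenchymal markers, 6 rose and 1 fell, also adjusted over the list alone (6 and 1; median 0.11; camera adjusted p = 0.0726, and 0.00778 without control replicate 2; range over its alternatives 0.00778 to 0.373). Acta2, smooth muscle actin, rose from 13845 ± 1188 to 24877 ± 558, Col3a1 by 0.80 and Zeb1 by 0.82 on the log2 scale, and Zeb2 fell by 0.87; Zeb1 did not pass as the mean of its probe sets (limma adjusted p = 0.128). Among 13 epithelial markers, Tjp1 rose by 0.41 and Cdh3 fell by 0.46, the same counts adjusted over the list alone (1 and 1; median −0.13; camera adjusted p = 0.618). Cdh3 did not pass without a variance trend, nor without miR-129 replicate 3 (0.079), control replicate 1 (0.0638) or control replicate 3 (0.0673). Of 9 alveolar type I markers, Cav1 (0.49), Cav2 (0.70), Pdpn (0.65) and Igfbp6 (0.55) rose, and 5 passed adjusted over the list alone (median 0.49; camera adjusted p = 0.153). Igfbp6 did not pass with no minimum, without a variance trend or without the arrays of extreme ratio, nor without miR-129 replicate 1 (0.0619), control replicate 1 (0.0787) or control replicate 3 (0.0611). Of 5 alveolar type II and club cell markers, Etv5 fell by 0.61 and Abca3 rose by 0.38, with the same counts adjusted over the list alone (1 and 1; median −0.25; camera adjusted p = 0.567). Abca3 did not pass without miR-129 replicate 1 (0.0612) or control replicate 1 (0.0746), and neither it nor Etv5 passed as means of their probe sets or without the arrays of extreme ratio. Of 6 fibroblast and endothelial markers, Postn rose from 1441 ± 85.0 to 4885 ± 264 and Dcn by 1.01, and Pdgfra (−0.57), Pdgfrb (−0.61) and Col6a1 (−0.30) fell, also adjusted over the list alone (2 and 3). Their median was −0.34 and their mean 0.15, with the test in the direction of the median (camera adjusted p = 0.901). Of 7 macrophage and leukocyte markers, Csf1r (0.76) and Lyz2 (0.78) rose and Cd14 (−0.36) fell, also adjusted over the list alone (2 and 1; median 0.08; camera adjusted p = 0.659). With the Gapdh ratio, which was higher with miR-129, as a covariate, Cdh3, Etv5, Abca3, Igfbp6, Lyz2, Cd14 and Pdgfra did not pass.

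Stress and metabolic lists did not pass camera, which compares a list with other genes, though single members changed by several fold. The fry test, which asks whether members move on balance in a direction without that comparison, passed for the unfolded protein (adjusted p = 0.00101), cholesterol (0.00108), glycolysis (0.000142) and NRF2 (0.00162) lists, and for 18 of all 24 lists. Dnajb9, a chaperone of the endoplasmic reticulum, rose from 1167 ± 52.4 to 4690 ± 392 (limma adjusted p = 2.53e-08), with Chac1 (0.99), Edem1 (0.76) and Xbp1 (0.51) also higher. Of 22 genes of the unfolded protein and integrated stress response, 10 rose and 2 fell, also adjusted over the list alone (10 and 2; median 0.22; camera adjusted p = 0.0524). Of 17 NRF2 targets, 9 rose and 2 fell, also adjusted over the list alone (9 and 2; median 0.27; camera adjusted p = 0.0524), and Ephx1, a detoxifying epoxide hydrolase, rose from 2904 ± 117 to 7495 ± 798. The stress response list passed without miR-129 replicate 3 (0.0326), control replicate 2 (0.0446) or control replicate 3 (0.0481), and the NRF2 list without miR-129 replicate 3 (0.0326) or control replicate 2 (0.0403). Over the alternatives their adjusted p ran from 0.0165, with no minimum, to 0.106 and 0.135. In cholesterol synthesis, 8 of 19 genes fell and 4 rose, also adjusted over the list alone (8 and 4; median −0.23; camera adjusted p = 0.0736, and 0.0446 without control replicate 2; range over its alternatives 0.0106, with the mean of the probe sets, to 0.169). Idi1 fell from 1284 ± 43.1 to 357 ± 33.3, Hmgcs1 by 1.07 and Mvd by 1.46 on the log2 scale, whereas Sc5d rose by 0.53 on its brightest probe set and was −0.30, not passing, as the mean of its probe sets. Of 21 glycolysis and hypoxia targets, 7 rose and 2 fell, also adjusted over the list alone (7 and 2; median 0.13; camera adjusted p = 0.0759, range over its alternatives 0.042, with no minimum, to 0.153), with Ero1a (1.32), Bnip3 (0.89), P4ha2 (0.86) and P4ha1 (0.79) higher. As means of their probe sets, P4ha1 (limma adjusted p = 0.533) and Xbp1 (0.19) did not pass. Of 21 ERK pathway and immediate early genes, 2 rose and 6 fell, also adjusted over the list alone (2 and 6; median −0.17; camera adjusted p = 0.243), with Dusp1 (1.36) higher and Egr1 (−1.16), Fosl1 (−0.50) and Junb (−0.63) lower; Junb did not pass with the Gapdh ratio as a covariate (limma adjusted p = 0.215). Of 15 cytosolic ribosomal proteins, Rps6 (−0.71) fell and 14 did not pass, with 1 passing adjusted over the list alone (median −0.02; camera adjusted p = 0.567).

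**Figure D2:**
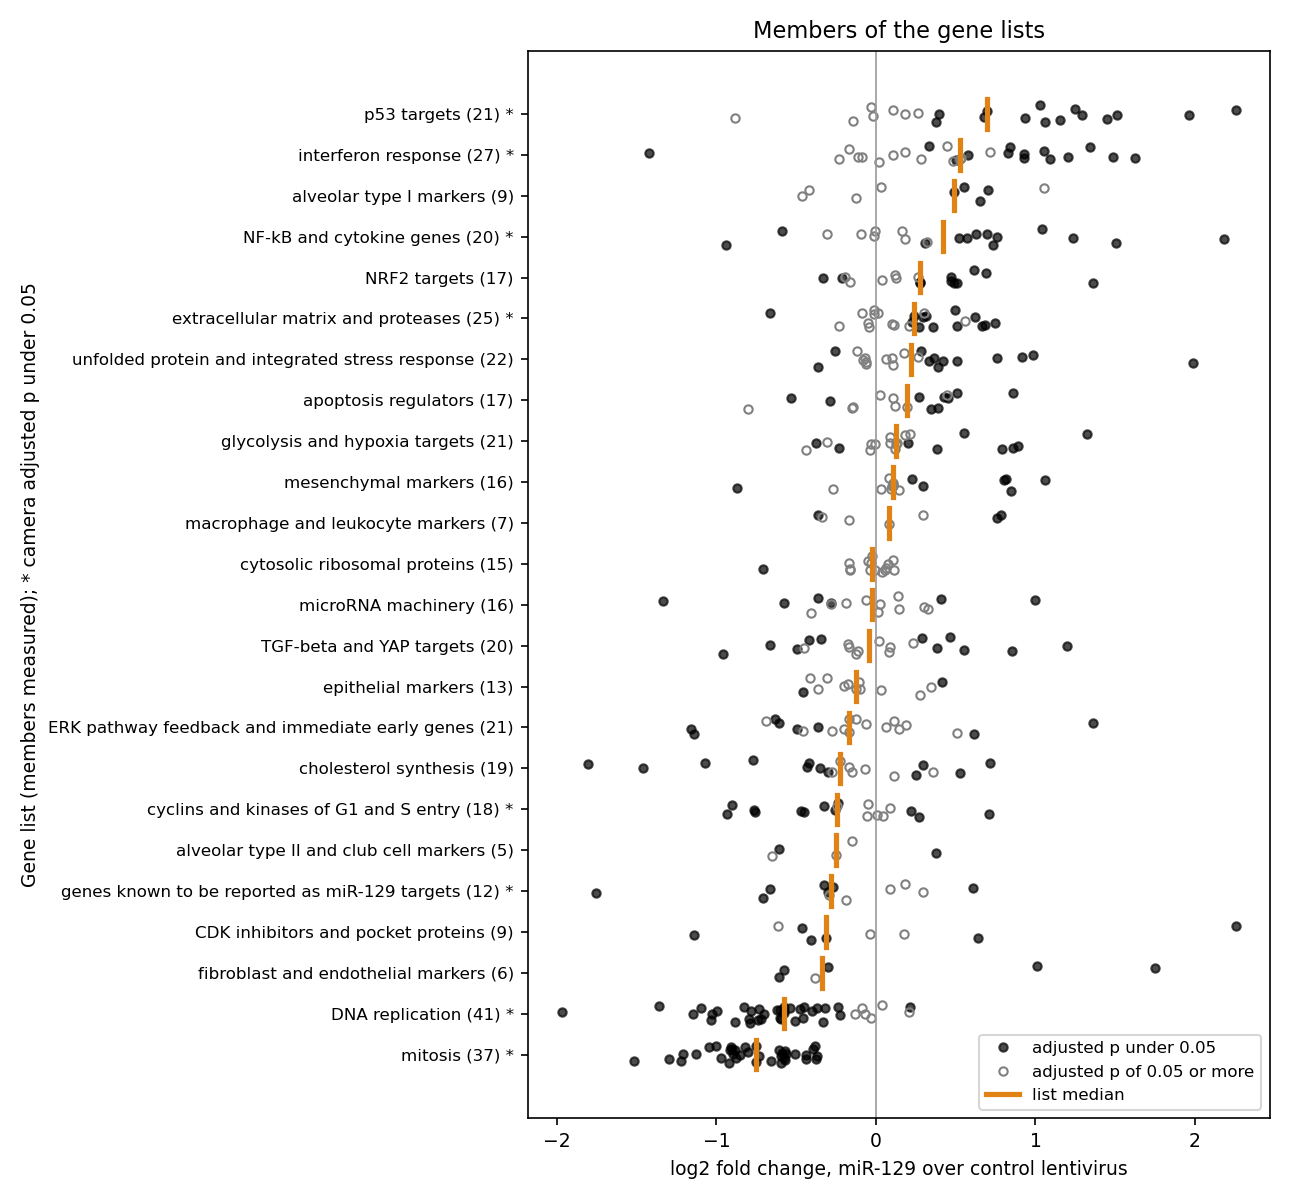
Log2 fold change of miR-129 over control lentivirus for the members of the 24 gene lists, with a point per gene, filled where the limma adjusted p was under 0.05, and a bar at the list median; the number of measured members stands in brackets and a star marks lists past camera. All 37 mitosis genes lie below 0, around a median of −0.75, and the p53 targets have a median of 0.69.

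**Figure D3:**
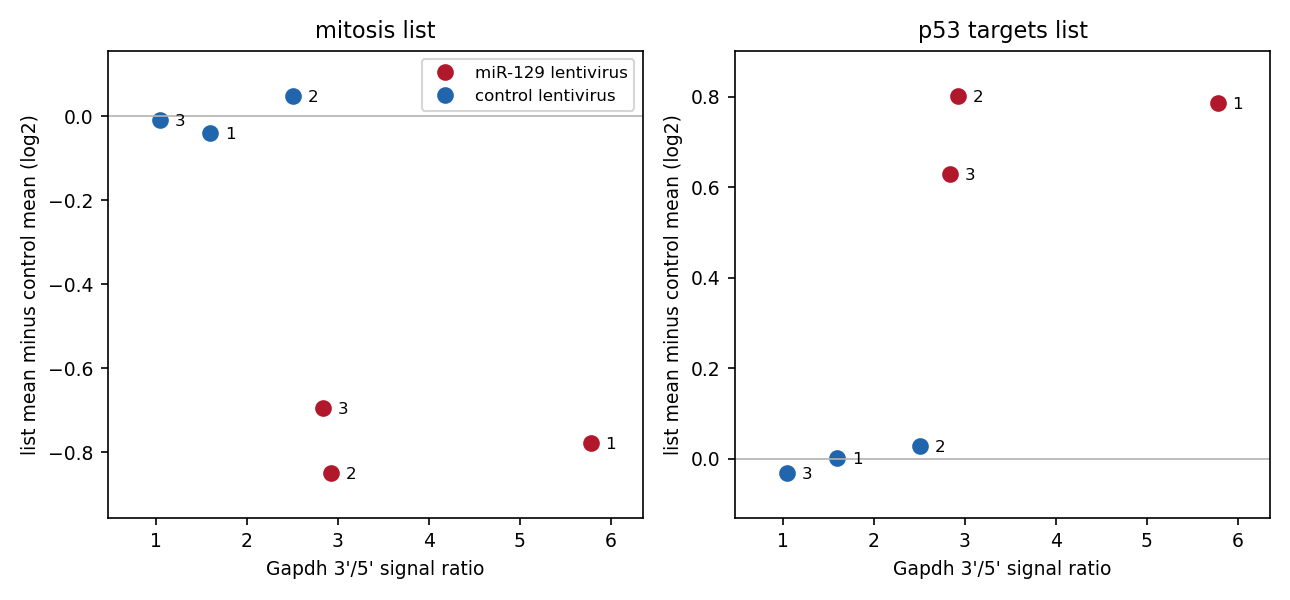
Mean log2 level of the mitosis list and of the p53 target list on each array, minus the control mean, against the Gapdh 3′ over 5′ ratio of that array, with points numbered by replicate. The miR-129 arrays lie at −0.69 to −0.85 for mitosis and at 0.63 to 0.80 for p53 targets, at ratios of 2.84 to 5.78.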

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

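The model with the Gapdh ratio as a covariate and the tests of the mitosis and p53 lists against array scaling were chosen only after the data were seen.

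Control probe sets outside the gene comparison stood apart between the groups. The Gapdh 3′ over 5′ ratio averaged 3.85 ± 1.67 on the miR-129 arrays and 1.72 ± 0.737 on the control arrays (SD, n = 3 each; exact permutation p = 0.1, the smallest possible here), and every miR-129 array lay above every control array. The same was true of the spiked-in lys transcript, at 4.60 ± 1.77 against 2.56 ± 0.290 (exact permutation p = 0.1), while Actb (5.57 against 3.94, exact permutation p = 0.2), dap (45.2 against 24.9, exact permutation p = 0.3) and phe (9.65 against 6.05, exact permutation p = 0.3) overlapped. Over 7 quality measures, the adjusted p of lys and Gapdh was 0.35.

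Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many changed genes: 5170, against at most 1 for any other split. With 10 splits the share cannot go under 0.1, so the splits are too few to settle the matter. Each other split also mixes the groups, so a difference between the groups widens the spread within it. Its low count is therefore no measure of chance. After quantile normalization 5186 genes changed. Without it, 2911 genes rose and 2259 fell at a median log2 fold change of 0.01, which argues against a common shift of all genes. The count could therefore hardly drop, and the normalization adds little to this. The balance of rises and falls did depend on scaling, since 65.4% of the changed genes rose after median-centring, against 56.3%.

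The fall of mitosis genes and the rise of p53 targets came together with the higher Gapdh ratio. With the log2 ratio in the model, the group term of the mitosis list mean was −0.796 (95% interval −1.086 to −0.507) and that of the p53 list mean was 0.668 (0.387 to 0.95), which argues against a trend with this ratio, whether from RNA quality or labelling, as the whole cause of these shifts. After quantile normalization the mitosis median lay at −0.80 and the p53 median at 0.616 from the median of all genes, which argues against scaling. A response to the miR-129 virus may underlie both shifts, but unequal infection or culture density, for which no measure was used here, stay open. No batch or date was given in the labels used here, so a batch that follows the groups could not be tested.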

How the results depend on the processing

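The covariate and the paired omission of extreme-ratio arrays were chosen after the data were seen; all other alternatives were planned. Mitosis, DNA replication, p53 targets, interferon response and NF-kB lists kept direction and call under these alternatives at the preset correlation of 0.01. With an estimated correlation, which was run once, only DNA replication kept its call (camera adjusted p = 0.046, against 0.178 for the other 4). The estimated correlations of the mitosis and p53 lists were 0.344 and 0.126. Those of the interferon and NF-kB lists were 0.00147 and 0.000582, below the preset 0.01, so a higher correlation does not explain their lost calls. The number of lists called was 8, 13 with no minimum, where more genes are tested, and 6 to 12 with each array left out, 6 without miR-129 replicate 2 and 12 without control replicate 2. The list of cyclins and kinases lost its call with a 60th percentile minimum (median −0.24, adjusted p = 0.0598), without a variance trend (−0.24, 0.0733), with the replicate block (−0.24, 0.056), with the mean of a gene's probe sets (−0.10, 0.103) and without the extreme-ratio arrays (−0.26, 0.0551), where fewer arrays enter. The reported miR-129 targets lost theirs without a trend (−0.28, 0.0733). With the mean of the probe sets, the matrix list (0.06, 0.122) and the reported miR-129 targets (−0.33, 0.103) also lost theirs, and Sc5d (−0.30), Bcl2l1 (−0.35) and Timp2 (−0.20) reversed without passing. The cause was not tested. Leaving out each array in turn, the median of the cyclin list ran from −0.27 to −0.20 and that of the reported targets from −0.31 to −0.19; the number of changed genes ran from 4248 to 4884 and of probe sets from 5882 to 7892. The Gapdh ratio as a covariate left 3798 changed probe sets (1976 higher, 1822 lower) and 2927 genes (1636 higher, 1291 lower), in a fit with fewer degrees of freedom. Without both extreme-ratio arrays, 5273 probe sets (2662 higher, 2611 lower) and 3784 genes changed, of which 3637 genes had been called in the same direction. The lists then had 37 mitosis and 32 replication genes lower and 14 p53, 11 interferon and 10 NF-kB genes higher. A 2-fold minimum left 1300 probe sets and 571 genes. Among the changed genes, 56.3% rose, 59.1% after quantile normalization, 65.4% after median-centring and 48.1% with the mean of the probe sets. Cdk6 was not called under any alternative. Of 1903 values of the 106 named genes under alternatives, 1863 kept direction and side of the threshold, 37 lost the call and 3 reversed. The labels do not say whether the shared replicate numbers pair the arrays, and 3 arrays per group are too few to settle it. The deviations of same-numbered arrays correlated at 0.13, −0.01 and 0.05, and 3 of 6 arrays correlated best with their own number. With the block 5270 genes and 8356 probe sets changed. The seed-match test was not run under any setting. Signals near the background limit the genes with the lowest control levels.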

Other observations

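The 6 gene lists of this part were written after the largest changes had been seen. Bysl, Nup98, Hnrnpa0 and Hsph1 had been seen to fall and Atp6v0d1 to rise, and most genes of the 2-cell stage list had been seen to rise, so those lists are not independent of the data. All tests of the 2-cell stage genes except that of pluripotent markers were chosen after the result was seen.

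Ribosome biogenesis genes fell, with 25 of 29 lower and 0 higher (25 adjusted over the list alone), at a median of −0.47 (camera adjusted p = 5.13e-11; adjusted p = 0.00904 with an estimated correlation). Bysl, needed for the small ribosomal subunit, fell from 2362 ± 117 to 798 ± 26.4, and Ddx21, a nucleolar helicase, from 5784 ± 647 to 2362 ± 485 (SD, n = 3 each). Nuclear pore and RNA-binding protein genes fell in 22 of 30 cases and Nup50 rose (23 and 1 adjusted over the list alone), at a median of −0.41 (camera adjusted p = 5.46e-09; adjusted p = 0.163 with an estimated correlation), with Hnrnpa0 (−1.62) and Nup98 (−1.52) lowest. Lysosome genes rose in 16 of 24 cases and fell in 0 (17 and 0 adjusted over the list alone), at a median of 0.33 (camera adjusted p = 7.6e-06; adjusted p = 0.163 with an estimated correlation). Neu1 (0.75), Glb1 (0.74), Atp6v0d1 (0.74) and Gla (0.70) led it. Of 19 cytosolic and mitochondrial heat shock proteins, 3 rose and 6 fell, as when adjusted over the list alone (3 and 6), at a median of −0.02. The list did not pass camera, which compares it with other genes (adjusted p = 0.352), and passed fry, which does not (adjusted p = 0.0406). Hsph1 fell by 1.99 and Fkbp4 by 0.78, while Hspa1b (1.19) and Cryab (0.93) rose. On the same arrays the Gapdh 3′ over 5′ ratio was higher with miR-129 (3.85 against 1.72).

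Genes known from the 2-cell mouse embryo rose in the miR-129 arrays. All 9 members above the minimum rose (9 adjusted over the list alone), at a median of 2.46 (camera adjusted p = 4.96e-05; adjusted p = 0.3 with an estimated correlation), which is no evidence of direction since the list was built on seen rises. AF067061 rose from 42.6 ± 34.7 to 1078 ± 583, Zfp352 from 36.6 ± 12.7 to 200.1 ± 81.7 on its brighter probe set, and Gm20767 by 3.60 on the log2 scale, while Duxf3 and Tdpoz1 were below the minimum. The minimum is set on the mean of all arrays, and 5 of the 9 genes passed it only through the miR-129 arrays: Gm20767 (control mean 5.77), Tcstv3 (7.57), Tcstv1 (17.4), BC080696 (17.5) and Pramel18. The count of 9 is therefore largely set by the minimum. All 10 called probe sets were lowest among the miR-129 arrays on replicate 3, with replicate 2 at 2.19 to 9.42 times its signal, and Sp110 had 463 and 141 on the same arrays. Replicate 3 also had the smallest shift over all called genes, though by far less. Its median log2 rise was 0.465, against 0.535 and 0.521 on replicates 1 and 2. Its median fall was −0.483, against −0.576 and −0.547.

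Carry-over of pluripotent cells stays open. The highest mean signal of a pluripotent marker on the miR-129 arrays was 60.2, against 72.3 in control, and 0 of the 5 measured markers changed (camera adjusted p = 0.556, median −0.22). The planned bound, the median signal of the 2-cell probe sets, was wrong, because levels of different probe sets are not comparable, and only 6 of 22 marker probe sets lay above the minimum. A trend with the Gapdh ratio alone would give miR-129 replicates 2 and 3, with ratios of 2.93 and 2.84, like signals. Replicate 2 had 2.19 to 9.42 times the signal of replicate 3 on the 10 called probe sets. This argues against the ratio as the whole cause of the signals on these arrays. How much of the group difference goes with the ratio cannot be told for all members: with the Gapdh ratio as a covariate 4 of the 9 genes passed. AF067061 had 2.80 ± 0.63 (SE) against 4.28 ± 0.53 without it, BC080696 1.53 ± 0.72 against 2.73 ± 0.53, Gm20767 3.03 ± 0.66 against 3.60 ± 0.43, and Pramel18 1.93 ± 0.78 against 2.34 ± 0.49. For the genes that did not pass, the estimate was smaller and the error wider. Sequence shared between the copies of these families also stays open, since the 10 probe sets could not be matched to sequences here.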
